A study of Homo sapiens with 12 samples.

How the data were processed

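The data are deposited tables of 12 libraries, 3 biological replicates in each of 4 groups, from HEK293T cells that carried a recorder mRNA library. Per the labels, PCR amplicons of the recorder 3′ UTR, which hold the element and the recorder hairpin, were sequenced. The labels' extraction text names another organism's embryos, while the source, cell line and series design give HEK293T, which is used here. Aligner, edit caller and read filters are not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

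Each deposited table lists per element 3 counts (reads, reads with at least 1 edit, and edits summed over reads) and the count of all reads of the library. The authors also deposited a percent of edited adenosines, a percent of all reads, and an efficiency score. Recomputed within 1e-09, the deposited percent edited equals the edits over 7 times the reads, which gives 7 recorder adenosines per read, and the score equals the share of reads edited times the edits per read. Every table lists only elements with over 1000 reads (lowest 1015), so 16 of the 1022 elements seen in any library were not listed in all 12 and were left out. The planned minimum of 100 reads per library therefore removed nothing. No molecular identifiers are mentioned in the labels, so reads may be PCR copies, and counting errors cover counting only. The typical counting error of an element's share of edited reads was 0.240 to 0.316 percentage points, and the variance between replicates was 2.73 to 5.79 times the binomial one, so replicate spread is used throughout. Replicate libraries of a group differed in read counts by 6.24 to 202 times sampling noise (chi-squared per degree of freedom), so none was counted as a duplicate.

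The value tested per element and library was log2((edits + 0.5)/(7 × reads − edits + 0.5)). Elements were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) in 1 fit of the 12 libraries, for 6 comparisons, with Benjamini-Hochberg adjustment over 1006 elements and a call at an adjusted p under 0.05. A second fit, also fixed in advance, centred each library on its median log2 odds. Its calls are reported as changes relative to the library median, because induction moved nearly the whole library. Library medians and the consensus preference were compared by two-sided exact permutation of 3 against 3 libraries, which cannot go below 0.10. Classes (TGTANATA, TGTA, TGT, no TGT, mismatches, ATTTA, TTTTT) were fixed before the data were examined, as were the main tests, the other settings tried and the rule for named elements. That rule takes the 4 consensus elements and EMPTY. For 250 ng against no induction it adds the 10 largest increases among called elements with all 3 induced libraries above all 3 others, and the 5 lowest changes. Against ADARcdMUT it adds the 5 largest changes each way by the same rule, and for ADARcdMUT against no induction the 5 largest either way. The families of single, double and reversed elements were formed after seeing which elements the library holds. Sets were tested with limma's camera (preset correlation 0.01, and an estimated one) on the planned absolute values and, after its results were seen, also on centred values, because the shift shared by a library raises the estimated correlation. Fry on centred values tests whether a set moves, on balance, one way, and does not compare it with other elements. Position effects came from least squares per library over the elements with at most 2 mismatches. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the rest.

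The fits were tested on simulated data with 200 of 1006 elements changed. The 2 compared groups were given the same base levels, and 1 variance ratio served for all elements and groups, unlike in the real libraries. For ADARcdMUT against no induction limma found 47% of changes of 0.25 and 99% of changes of 0.5 in log2 odds, with 22 false calls (13.1% of calls), more than the nominal share. For 250 ng against 25 ng it found 57% and 98% with 0 false calls. The position model returned simulated effects within 0.00996 log2 odds. Those effects were simulated as adding up over positions, so the check does not show that they add up in the real data. The values in the Results argue against it. Alternatives tried were other pseudocounts, read minimums, a quasi-binomial model in R, the arcsine square root scale, the share of edited reads, the deposited score, fits of only 2 groups, the replicate number as a block, and each library left out in turn. Alternatives applied to the centred values, the minimum of 5000 reads and the score were exceptions, added after seeing the data.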

Results

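RBPscan reads out where an RNA-binding protein sits on an RNA inside living cells by the edits that a fused deaminase leaves nearby. The protein studied here was human PUM2, a Pumilio-family repressor that binds the Pumilio response element TGTANATA (DNA letters, N being any base). It was fused to a mutated catalytic domain of ADAR (ADARcdMUT), an enzyme that turns adenosine into inosine. Inosine is read as G, so editing appears as A-to-G changes. The reporter was a library of mRNAs that each carried 1 short element beside a recorder hairpin in the 3′ UTR, expressed in HEK293T, a human embryonic kidney cell line. Per the labels there were 4 groups of 3 biological replicates: the fusion without induction, the fusion at 25 ng, the fusion at 250 ng, and ADARcdMUT without PUM2 at 1000 ng. The amounts are those in the sample titles, which give no volume and no substance. Whether the 1000 ng of the ADARcdMUT-only libraries refers to the same substance as the other amounts is not given in the sources used here. The series states that the fusion was induced with doxycycline, a drug used to switch on transgenes. The 12 libraries held 11235321 to 25127959 reads, of which the listed elements took 99.7% to 99.8%. The median number of reads per listed element was 10214 to 23712.

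The 1006 elements listed in all 12 libraries were 1005 sequences of 8 bases and an entry named EMPTY, whose content is not given in the sources used here. The 8-base elements were the 4 forms of TGTANATA, all 84 single and all 756 double substitutions of its 7 fixed positions, 88 elements that read as the reversed consensus with at most 1 mismatch, and 73 others. By sequence, 4 were consensus elements, 181 held TGTA without being consensus, 168 held TGT but not TGTA, and 652 had no TGT. The editing level is the percent of the 7 recorder adenosines that were edited, over all reads of an element.

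Induction of the fusion at 250 ng against no induction asked which elements gain editing once PUM2-ADARcdMUT is made. The consensus elements rose most: their median level went from 1.79% ± 0.0794 (SD, n = 3) without induction to 13.3% ± 0.288 at 250 ng, a 7.45-fold rise. Elements with TGTA outside the consensus rose from 1.82% ± 0.101 to 8.45% ± 0.0724, those with TGT but not TGTA from 1.86% ± 0.114 to 7.85% ± 0.0928, and those without TGT from 1.81% ± 0.0969 to 7.80% ± 0.0961, a 4.31-fold rise. EMPTY rose less, from 2.01% ± 0.111 to 7.63% ± 0.0689, a 3.802-fold rise. The median over the 8-base elements of a library was 1.82% ± 0.0991 without induction and 7.87% ± 0.0992 at 250 ng, a difference of 6.05 percentage points (two-sided exact permutation p = 0.10, the smallest that 3 against 3 libraries allow; adjusted p = 0.12 over 6 comparisons). In limma's moderated fit all 1006 elements were higher and 0 lower, and the median log2 odds of editing rose by 2.21.

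**Figure D1:**
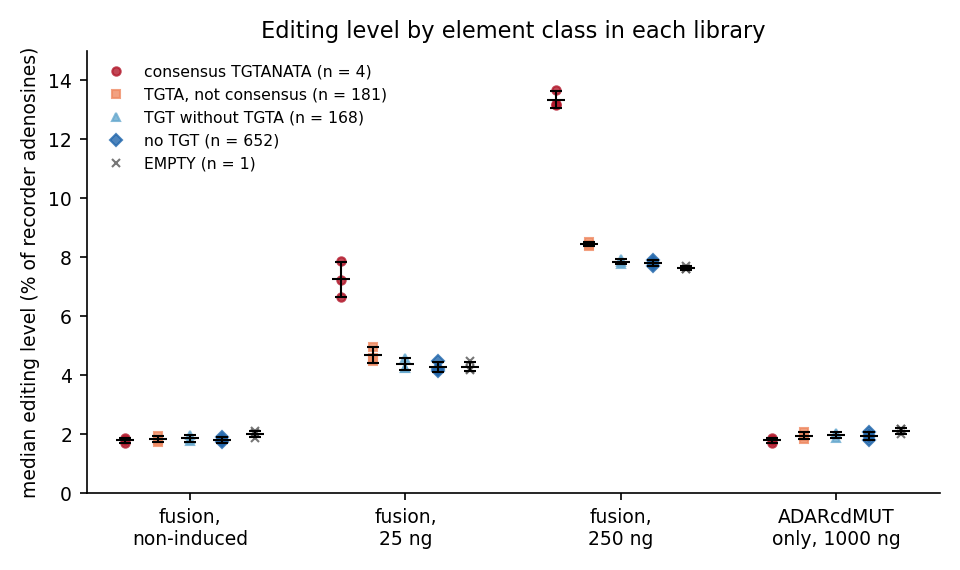
Median editing level of each element class (percent of recorder adenosines, vertical axis) in the 3 libraries of each group (horizontal axis); points are libraries and black bars the mean ± SD. The consensus elements stand apart at 25 ng and 250 ng, at 7.24% and 13.3%, while all classes lie near 1.8% to 2.1% without induction and with ADARcdMUT alone.

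All 4 consensus elements were among the 10 largest increases at 250 ng. TGTATATA rose from 1.81% ± 0.186 to 13.9% ± 0.360 (log2 odds change 3.13, SE 0.11, limma adjusted p = 2.88e-19), TGTAAATA from 1.78% ± 0.156 to 13.2% ± 0.328, TGTACATA from 1.88% ± 0.137 to 13.4% ± 0.379 and TGTAGATA from 1.75% ± 0.162 to 11.5% ± 0.195. The other 6 kept TGTA at the start and differed from the consensus at positions 7 or 8, counted from 1 at the 5′ end of the element. With A8T, TGTATATT reached 11.8% ± 0.481, TGTACATT 11.5% ± 0.0835 and TGTAAATT 11.1% ± 0.318. TGTACAAA, with T7A, reached 11.3% ± 0.309, and 2 elements with both positions changed followed, TGTACAGG (T7G and A8G) at 11.2% ± 0.103 and TGTACAGT (T7G and A8T) at 11.5% ± 0.415. The 5 smallest increases were those of ATTGATGT, TGTGTGTG, ATACGTGT, TGTCCAGA and TGGATAGA, with log2 odds changes from 1.79 to 1.90. These elements had the higher starting levels, such as 2.42% ± 0.273 for ATTGATGT, and reached 7.52% to 8.05% at 250 ng.

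Because the whole library rose, changes were also taken relative to each library's median log2 odds. On this scale 97 elements were higher and 34 lower at 250 ng in limma. All 4 consensus elements were higher, by 0.93 (SE 0.12) for TGTATATA, 0.87 (SE 0.10) for TGTAAATA, 0.82 (SE 0.08) for TGTACATA and 0.67 (SE 0.06) for TGTAGATA. Of the 181 TGTA elements 63 were higher and 1 lower (80 and 3 adjusted over the list alone), and of the 84 single substitutions 46 were higher and 1 lower (54 and 1 adjusted over the list alone). Among 168 elements with TGT but not TGTA 8 were higher and 10 lower (5 and 8 adjusted over the list alone), and among 652 without TGT 22 were higher and 22 lower (10 and 7 adjusted over the list alone). No reversed element was higher and 7 of 88 were lower (0 and 2 adjusted over the list alone). None of the 13 elements with ATTTA, the core of AU-rich elements, nor of the 2 with TTTTT passed in either direction by limma, at medians of 0.06 and 0.07. The lowest relative values were those of ATTGATGT at -0.42, TGTGTGTG at -0.36, ATACGTGT at -0.33, TGTCCAGA at -0.32 and TGGATAGA at -0.31, and EMPTY was at -0.19 (limma adjusted p = 0.0139). Leaving out fusion 250 ng replicate 1, 2 or 3 left 13, 13 and 12 lower elements, and a fit of only these 2 groups gave 132 higher and 67 lower. On the arcsine square root scale 153 were higher and 63 lower.

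As a class, the consensus elements rose more than the others in camera, a competitive set test (preset correlation, adjusted p = 5.20e-05; adjusted p = 0.0471 with an estimated correlation). The TGTA class (preset adjusted p = 8.25e-07) and the single substitutions (2.77e-05) also rose more, but on the absolute scale both calls were lost with an estimated correlation (adjusted p = 0.822 for each). Downward calls were lost as well: reversed elements (0.000139; adjusted p = 0.822 with an estimated correlation), elements without TGT (0.000506; 0.868), other elements (0.0328; 0.868), and those with 3 (5.32e-06; 0.123) or at least 4 mismatches (0.00263; 0.868). On values centred on the library medians, a setting added after the data were seen, camera with an estimated correlation gave adjusted p = 0.00139 for the consensus class, 3.61e-05 for the TGTA class and 3.61e-05 for the single substitutions, all upward, and 0.0203 for the reversed elements, downward. The class with TGT but not TGTA (median -0.02, adjusted p = 0.0333) and the class without TGT (median -0.00, adjusted p = 0.00161) ranked lower than the other elements, which the rise of the TGTA class can give in a competitive test. In fry, which tests whether a set moves one way, neither passed (adjusted p = 0.0649 and 0.362). The consensus preference, the median log2 odds of consensus elements minus that of elements without TGT in the same library, was -0.02 ± 0.13 (SD, n = 3) without induction and 0.86 ± 0.02 at 250 ng, an odds ratio of 1.82 (two-sided exact permutation p = 0.10, adjusted p = 0.15 over 6 comparisons).

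Induction at 25 ng against no induction asked whether the same elements stand out at the lower amount. Consensus elements rose to 7.24% ± 0.603 (SD, n = 3), 4.04-fold over the non-induced level, against 4.68% ± 0.261 for TGTA elements and 4.29% ± 0.172 for elements without TGT. TGTACATA was at 7.55% ± 0.737, TGTAAATA at 7.30% ± 0.658, TGTATATA at 7.28% ± 0.593 and TGTAGATA at 6.10% ± 0.190. The library median was 4.35% ± 0.194, a difference of 2.52 points (two-sided exact permutation p = 0.10, adjusted p = 0.12), and limma called all 1006 elements higher and 0 lower, with a median log2 odds change of 1.29. Relative to the library median 71 elements were higher and 22 lower, and all 4 consensus elements were among the higher. Of 181 with TGTA 50 were higher and 1 lower (66 and 2 adjusted over the list alone). The counts were 35 higher and 0 lower of 84 single substitutions (44 and 1 adjusted over the list alone), and 12 higher and 15 lower of 652 without TGT (3 and 0 adjusted over the list alone). On absolute values camera called the consensus class (preset adjusted p = 8.55e-08; adjusted p = 0.00929 with an estimated correlation) and the TGTA class (2.96e-09), which was lost (adjusted p = 0.738 with an estimated correlation). Also called and lost were the single substitutions upward (5.32e-09; 0.724) and, downward, reversed elements (3.21e-05; 0.738), elements without TGT (3.21e-05; 0.813) and those with 3 (3.21e-05; 0.215) or at least 4 mismatches (0.00121; 0.836). On centred values with an estimated correlation the adjusted p was 0.000899 for the consensus class and 3.50e-05 for the TGTA class, and 0.0939 for the class with TGT but not TGTA, which did not pass. Called downward were the class without TGT (0.000899), reversed elements (0.0344) and double substitutions (0.00319). Of these, fry called the reversed elements (adjusted p = 0.0147), but not the class without TGT (0.0898) or the double substitutions (0.762). The consensus preference was 0.80 ± 0.08, an odds ratio of 1.74 (difference from non-induced 0.82, two-sided exact permutation p = 0.10, adjusted p = 0.15). The count of 22 lower elements fell to 9 without non-induced replicate 1 or 3, and to 4, 3 and 6 without fusion 25 ng replicate 1, 2 or 3.

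The comparison of 250 ng with 25 ng asked whether a larger amount raises editing evenly. Consensus elements gained 11.5 points over the non-induced level at 250 ng and 5.45 points at 25 ng, and elements without TGT gained 5.99 and 2.48 points. The gain of consensus elements divided by that of elements without TGT was 2.20 ± 0.111 (SD, n = 3) at 25 ng and 1.93 ± 0.0303 at 250 ng, a ratio formed after the values were seen (two-sided exact permutation p = 0.10, the smallest possible). The consensus preference in log2 odds was 0.06 higher at 250 ng (two-sided exact permutation p = 0.20, adjusted p = 0.24), and 0.02 higher without fusion 25 ng replicate 3. All 1006 elements were higher and 0 lower at 250 ng in limma, with a median change of 0.92, and the library median was 3.53 points higher (two-sided exact permutation p = 0.10, adjusted p = 0.12). Relative to the library median limma called 0 elements, with 4 at an unadjusted p under 0.05, and 0 with 77 when only the 2 groups entered the fit. The 4 are fewer than chance alone gives at that threshold, so the 0 calls are weak evidence that no element differed. On simulated data of the same size the centred fit found 59% of changes of 0.25 and 98% of changes of 0.5 in log2 odds. That simulation gave both groups the 25 ng levels and 1 variance ratio, so it may overstate what the real fit can find. On the arcsine square root scale 35 elements were higher relative to the median. As a class the TGTA elements were 0.03 higher in median and the single substitutions, which share members with them, 0.04 (camera on centred values, adjusted p = 0.0189 and 0.0393 with an estimated correlation), while the consensus class did not pass (adjusted p = 0.241). In points TGTA elements and single substitutions also rose more than elements without TGT from 25 ng to 250 ng. Their gains over no induction went from 2.85 to 6.62 and from 3.05 to 7.11, against 2.48 to 5.99. Only as a ratio was the order the other one. The gain at 250 ng was 2.32 times that at 25 ng for TGTA elements, 2.33 for single substitutions and 2.42 for elements without TGT. On absolute values the planned camera called the TGTA class upward and the reversed elements downward (preset adjusted p = 0.0448 for both; adjusted p = 0.932 with an estimated correlation). It called the 14 elements with 3 mismatches downward (5.32e-05; adjusted p = 0.334 with an estimated correlation) and did not call the single substitutions (0.625).

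The ADARcdMUT-only libraries ask what the catalytic domain edits without PUM2. They differ from the fusion libraries in construct and in the amount their titles give, which may not be on 1 scale, and protein levels are not given in the sources used here. With ADARcdMUT alone the consensus elements were at 1.80% ± 0.0878 (SD, n = 3), the TGTA elements at 1.94% ± 0.121, the elements without TGT at 1.94% ± 0.124 and EMPTY at 2.12% ± 0.109. Against these, fusion at 250 ng was higher by 5.93 points in the library median and fusion at 25 ng by 2.40 points (two-sided exact permutation p = 0.10 and adjusted p = 0.12 for both). The 5 largest increases of the 250 ng fusion over ADARcdMUT were TGTATATA (log2 odds change 3.31, SE 0.11), TGTACATA (3.18, SE 0.11), TGTAAATA (3.02, SE 0.11), TGTACAGG (2.85, SE 0.09) and TGTATATT (2.82, SE 0.11), each with a limma adjusted p of at most 1.86e-18. Limma called all 1006 elements higher and 0 lower in both comparisons, with median changes of 2.12 and 1.19, so none met the rule for a decrease. The consensus preference with ADARcdMUT alone was -0.11 ± 0.02, which was 0.98 below the 250 ng fusion and 0.91 below the 25 ng fusion (two-sided exact permutation p = 0.10, adjusted p = 0.15 for both).

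**Figure D2:**
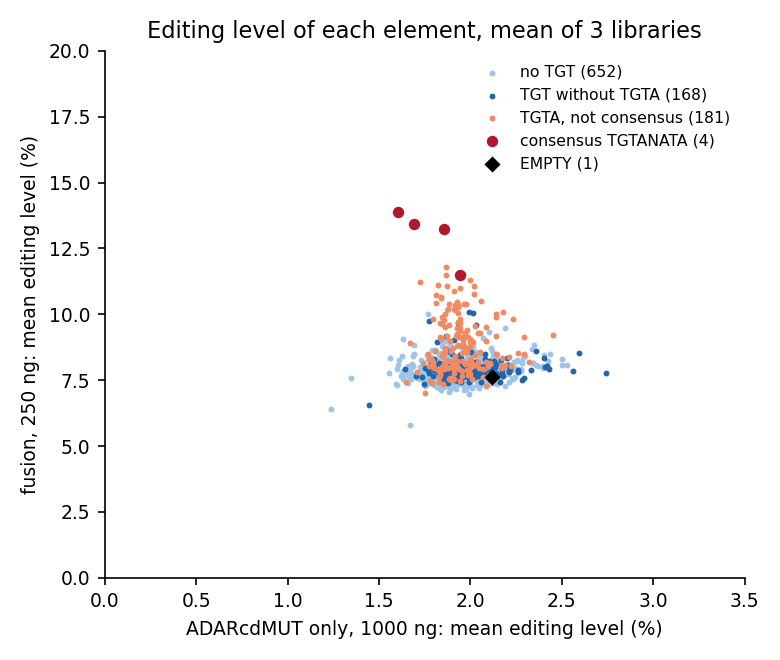
Mean editing level over 3 libraries of each of the 1006 elements with ADARcdMUT alone (horizontal axis, percent) and with the fusion at 250 ng (vertical axis, percent), coloured by class with the number of elements in brackets. Consensus elements and many TGTA elements extend upward, TGTATATA to 13.9%, while along the horizontal axis the consensus elements lie between 1.60% and 1.94%.

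Relative to the library median, 104 elements were higher and 44 lower in the 250 ng fusion than with ADARcdMUT alone. All 4 consensus elements were higher, as were 65 of 181 TGTA elements with 1 lower (79 and 3 adjusted over the list alone) and 42 of 84 single substitutions with 1 lower (49 and 1 adjusted over the list alone). At 25 ng 76 were higher and 25 lower, and all 4 consensus elements were higher. So were 53 of 181 TGTA elements (65 higher and 1 lower adjusted over the list alone) and 31 of 84 single substitutions with 1 lower (41 and 1 adjusted over the list alone). On absolute values camera called the consensus class at 250 ng (preset adjusted p = 1.10e-05; adjusted p = 0.0239 with an estimated correlation) and at 25 ng (1.30e-08; 0.00566). The TGTA class was called at 250 ng (3.45e-07) and 25 ng (1.39e-09) and lost at both (adjusted p = 0.831 and 0.783 with an estimated correlation). Lost at 250 ng were also the single substitutions upward (0.000124; 0.831) and, downward, reversed elements (0.00015; 0.831), elements without TGT (0.00032; 0.831) and those with 3 (0.00472; 0.749) or at least 4 mismatches (0.00472; 0.831). Lost at 25 ng were the single substitutions (1.39e-07; 0.783), reversed elements (4.87e-05; 0.783), elements without TGT (2.46e-05; 0.783) and those with at least 4 mismatches (0.00461; 0.820). On centred values with an estimated correlation the adjusted p was 0.00104 for the consensus class at 250 ng and 0.000745 at 25 ng, and 5.02e-05 and 6.89e-05 for the TGTA class. Counts at 250 ng were 68 and 14 without fusion 250 ng replicate 1, 73 and 16 without replicate 2 and 69 and 12 without replicate 3. They were 82 and 20 with only the 2 groups in the fit, and 160 and 69 on the arcsine square root scale. The lower count at 25 ng was 15, 9 and 12 without fusion 25 ng replicate 1, 2 or 3, 41 and 43 without ADARcdMUT replicate 1 or 2, and 6 with only the 2 groups in the fit.

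ADARcdMUT alone against the non-induced fusion compares the background of both constructs. The library medians were 1.95% ± 0.120 and 1.82% ± 0.0991 (SD, n = 3), a difference of 0.123 points with overlapping replicates (two-sided exact permutation p = 0.20, adjusted p = 0.20). It was 0.0661 without ADARcdMUT replicate 1, 0.186 without ADARcdMUT replicate 3 and 0.0773 without non-induced replicate 1. Limma called 2 elements higher and 0 lower, with 177 at an unadjusted p under 0.05, and 2 higher and 0 lower relative to the library median, with 134. TATAATTA (G2A and A6T) was at 1.64% ± 0.101 without induction and 2.28% ± 0.206 with ADARcdMUT (log2 odds change 0.49, SE 0.09, limma adjusted p = 0.00943), and TTTACAAA (G2T and T7A) at 1.58% ± 0.103 and 2.14% ± 0.221 (0.45, SE 0.09, limma adjusted p = 0.0183). In the fusion at 250 ng both were near the library median, at 8.16% ± 0.455 and 8.06% ± 0.181. No consensus element was called over all elements, 1 of 4 was lower relative to the library median when adjusted over the list alone, and the consensus preference differed by -0.10 (two-sided exact permutation p = 0.40). That difference was -0.06 without non-induced replicate 1 or 3 and -0.17 without non-induced replicate 2. Among the sets, camera on absolute values called the 14 elements with 3 mismatches lower (preset adjusted p = 0.00255; adjusted p = 0.517 with an estimated correlation). Both calls ended in a fit of only these 2 groups and in a quasi-binomial model, which gave 0 calls each (74 and 77 at an unadjusted p under 0.05), and 13.1% of limma's calls were false in simulated data for this comparison. The count was 0, 5 and 1 without non-induced replicate 1, 2 or 3, and 0 and 118 without ADARcdMUT replicate 2 or 3.

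Substitutions in the consensus asked which of its bases the editing signal needs. At 250 ng the consensus elements averaged 13.0% ± 0.227 (SD over libraries, n = 3) and every single substitution, averaged over the 4 bases at position 5, lay below. Changes at positions 1 and 3 took levels close to that of elements without TGT (7.80%): 8.31% ± 0.175 at position 1 and 8.17% ± 0.114 at position 3, which kept 9.87% ± 1.71 and 7.06% ± 0.325 of the consensus excess over elements without TGT. Position 2 kept 17.9% ± 3.26, position 4 28.6% ± 0.984, position 6 32.3% ± 0.449, position 7 34.1% ± 0.966 and position 8 45.4% ± 1.55. Levels differed by the base put in. A8T stayed at 10.96% ± 0.218 and A8C at 9.48% ± 0.145, T7A at 10.4% ± 0.214 and T7C at 8.46% ± 0.154, and G2A at 9.57% ± 0.346 and G2C at 8.12% ± 0.230. Relative to the library median, limma called 11 of 12 elements with a change at position 8 higher in the 250 ng fusion than without induction. The counts were 8 of 12 at position 7, 9 of 12 at position 6 and at position 4, 5 at position 2, 3 at position 1 and 1 at position 3. The 1 single substitution that was lower was TGGATATA (T3G), at 2.25% ± 0.0441 without induction and 8.08% ± 0.0725 at 250 ng, singled out after its values were seen. At 25 ng the shares kept were 9.48% ± 0.602 at position 1, 8.06% ± 2.86 at position 3 and 42.0% ± 0.492 at position 8.

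**Figure D3:**
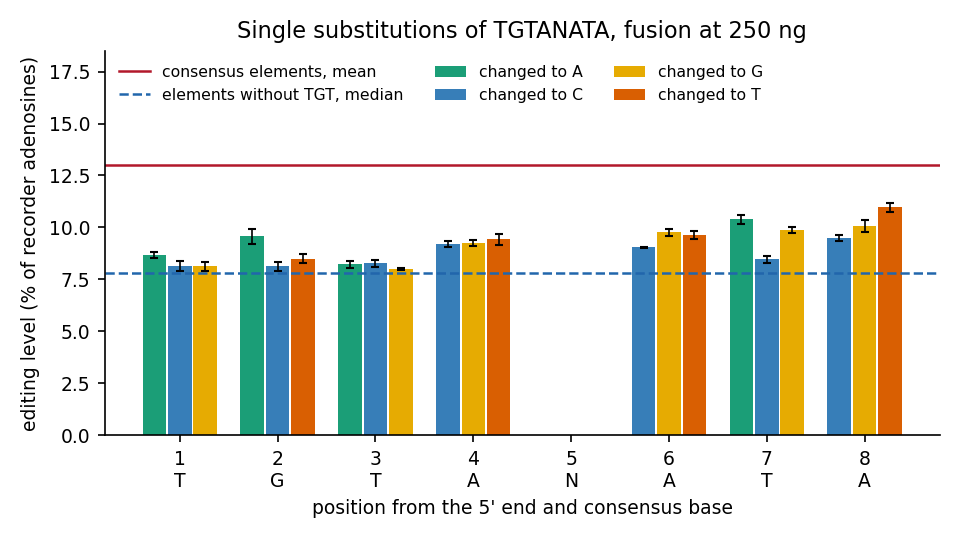
Editing level (percent, vertical axis) in the fusion at 250 ng for each single substitution by position from the 5′ end (horizontal axis, with the consensus base); bars are means over 4 elements and 3 libraries, error bars the SD over libraries. Averaged by position, changes at positions 1 (8.31%) and 3 (8.17%) lie nearest the dashed line for elements without TGT (7.80%), and A8T is the highest bar at 10.96%.

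A least-squares model over the 844 elements with at most 2 mismatches put the consensus base above the mean of the other bases at each of the 7 fixed positions at 250 ng, by 0.21 ± 0.01 log2 odds at position 8 to 0.28 ± 0.01 at position 1 (mean ± SD, n = 3). Without induction the same effects were between -0.05 and 0.02, and with ADARcdMUT alone between -0.05 and -0.00. The differences between 250 ng and no induction were 0.23 to 0.31 (two-sided exact permutation p = 0.10 for each, adjusted p = 0.131 over 42 tests). Over consensus elements and single substitutions alone the effects at 250 ng were larger, from 0.41 ± 0.02 at position 8 to 0.75 ± 0.03 at position 3. Effects that add up in log2 odds would be alike in both sets of elements, so these values argue against adding up. The effects over the 844 elements are averages over elements with and without a further change, and do not show that positions matter equally. At the free position 5, the effect of G was -0.08 ± 0.01 and that of T 0.10 ± 0.01 in the 844 elements at 250 ng, each against the mean of the other bases. Among the consensus elements TGTAGATA was lower than the mean of the other 3 in 6 of 6 induced libraries, by -0.28 ± 0.06 log2 odds (two-sided exact sign-flip permutation p = 0.0312, the smallest for 6 libraries; a test chosen after the values were seen). In the 6 other libraries the difference was 0.06 ± 0.18 (exact sign-flip permutation p = 0.406), made up of -0.06 ± 0.16 without induction and 0.19 ± 0.09 with ADARcdMUT alone.

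Double substitutions had a median of 7.83% ± 0.0924 (SD, n = 3) at 250 ng. They make up 525 of the 652 elements without TGT, so the medians of both groups are close by construction. Of 756 double substitutions, 40 were higher and 22 lower relative to the library median at 250 ng against no induction (32 and 17 adjusted over the list alone), and 13 of the 40 had their changes at positions 7 and 8. The pair of positions 7 and 8 lay 0.21 ± 0.01 log2 odds above elements without TGT (8.96% ± 0.115, SD, n = 3), and the other 20 pairs, most of which change a base of TGT and so fall largely into the reference, at most 0.05 above. With T7A, a further change at position 8 took the level from 10.4% ± 0.214 to 8.76% ± 0.0956, whereas with T7G it went from 9.88% ± 0.136 to 9.74% ± 0.176. The loss from changing position 8 was 0.25 ± 0.02 log2 odds with T7A, 0.03 ± 0.03 with T7G and 0.03 ± 0.02 with T7C over the 6 induced libraries. Each loss was above 0 in 6 of 6 (two-sided exact sign-flip permutation p = 0.0312 for each). T7C without a change at position 8 lay only 0.13 above elements without TGT at 250 ng, so it had little left to lose. The difference between T7A and T7G of 0.22 ± 0.04 was above 0 in 6 of 6 (two-sided exact sign-flip permutation p = 0.0312, the smallest possible). These comparisons were chosen after the values were seen.

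**Figure D4:**
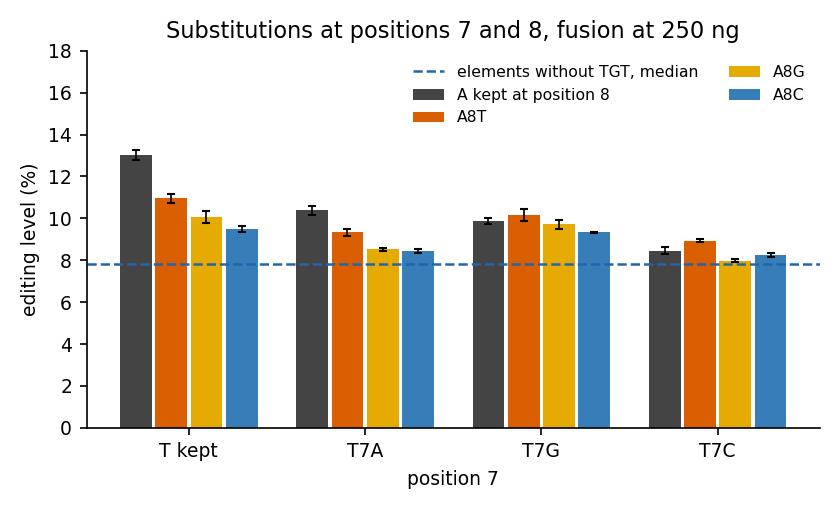
Editing level (percent, vertical axis) in the fusion at 250 ng by the base at position 7 (horizontal axis) and at position 8 (colours); bars are means over 4 elements and 3 libraries, error bars the SD over libraries. With T7G the 4 bars stay between 9.33% and 10.2%, with T7A they go from 10.4% to 8.42%.

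The ranking of elements was shared between the induced groups. Across the 1005 8-base elements, which are not independent replicates, group means of log2 odds correlated with r = 0.920 (Spearman 0.767) between 25 ng and 250 ng. Either induced group correlated at 0.0427 to 0.178 with the non-induced and ADARcdMUT-only groups, and those at 0.559 with each other. Replicate libraries correlated at 0.923 to 0.939 at 250 ng, 0.714 to 0.818 at 25 ng, 0.340 to 0.407 without induction and 0.226 to 0.291 with ADARcdMUT alone.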

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

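The splits of the libraries and the differences in log2 odds between amounts follow planned fits, but the class test on centred values, the read shares and all tests of explanations in this part were chosen after the results were seen, and so were the bounds set for those explanations.

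The rise from no induction to 250 ng and to 25 ng differed between the 2 amounts for a pair of overlapping element groups, relative to the library median. Single substitutions that keep TGTA count in both, so the 2 results are not independent. The TGTA class was 0.0266 higher in median log2 odds at 250 ng than at 25 ng and the single substitutions 0.0359, by a test of the difference itself on centred values (camera, adjusted p = 0.0189 and 0.0393 with an estimated correlation; fry, which tests whether a set moves one way, adjusted p = 0.0153 and 0.0391). In points both groups also rose more than elements without TGT from 25 ng to 250 ng. The gains over no induction went from 2.85 to 6.62 for the TGTA class and from 3.05 to 7.11 for single substitutions, against 2.48 to 5.99. As a ratio the order turns: the gain at 250 ng was 2.32 times that at 25 ng for the TGTA class and 2.33 for single substitutions, under the 2.42 of elements without TGT. No single element of either group was called by limma on log2 odds (4 of all elements at an unadjusted p under 0.05, and 77 with only the 2 groups in the fit). The 4 are fewer than chance alone gives. On the arcsine square root scale 35 of all elements were higher relative to the median. The planned camera on absolute values lost the TGTA call with an estimated correlation (adjusted p = 0.932).

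Read numbers enter the editing level only as its denominator, and their shares were compared here by base composition. The exact tests of 3 against 3 libraries cannot go below 0.10, so none could pass. Between 250 ng and no induction the difference in log2 share fell with each further G or C. It was 0.107, 0.0452 and -0.0157 for elements with 1, 2 and 3. The log2 share of reads of the 37 elements with 0 G or C was 0.16 higher at 250 ng than without induction (exact permutation p = 0.20), and that of the 134 elements with 4 G or C changed by -0.0871 (exact permutation p = 0.10), each with adjusted p = 0.30 over 15 tests. At 25 ng the differences from no induction were -0.0101 and -0.0178 (exact permutation p = 0.80 and 0.70), and with ADARcdMUT alone -0.17 and 0.16 (exact permutation p = 0.20 and 0.10, adjusted p = 0.30 for both). No explanation was tested.

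Elements without any TGT gained 5.99 points at 250 ng although they hold no consensus Pumilio element. The catalytic domain at its ADARcdMUT-only level is argued against as the whole cause, since it gained 0.129 points (SE 0.0910) there, though protein amounts were not measured. Partial Pumilio elements read from the first base are argued against as the whole cause. Elements without TGT at 4 or more mismatches gained 6.02 points (84 elements) and those at 2 mismatches 5.96 (525 elements). Mismatches were counted from the first base alone, so partial elements that start later are not covered. Reads swapped between elements would need a share of 96.0% and would hold every element above 7.73%. Of the 652 elements, 67 lay more than 3 SE under that level, and simulated normal draws gave at most 5. The same SE of 0.0868 points served for all elements in both counts. Elements with more spread than that can fall under the level by chance more often. Sites elsewhere in the reporter, the sequence around the element, a smaller share of swapped reads and a higher level of fusion protein may contribute and were not tested.

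The 33 elements of 8 bases that were lower relative to the library median at 250 ng were all higher in percent than without induction, and 32 of them lack TGTA. High values by chance without induction are argued against as the whole cause by the ADARcdMUT-only libraries. The levels of those libraries did not enter the change the elements were chosen by, though their spread entered the fit. There the same elements lay 0.13 log2 odds above elements without TGT, against 0.23 without induction. The SE of 0.03 was taken over the 33 elements and holds no spread between libraries. A stricter bound, dropped once the value was seen, left this explanation open, and the smaller value with ADARcdMUT leaves room for chance as part of the cause. A background that adds to the fusion's editing (gain of 5.603 points against 5.97) and less editing than other elements once the fusion is induced (-0.0169 log2 odds from elements without TGT at 250 ng, 13 of 33 above) may each contribute. They cannot be told apart, because both values were measured on elements chosen for a small change to 250 ng. No biological explanation was tested.

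With 3 against 3 libraries there are 10 splits, so a share under 0.05 cannot be reached for any comparison. The real split alone, 1 of 10, gave 1006 calls in each of the 5 comparisons with induced fusion, and the highest other split gave 0, which follows from mixing groups with such different library levels and is no evidence on chance. Relative to the library median the real split alone gave 131 calls for 250 ng and 93 for 25 ng against no induction, and 148 and 101 against ADARcdMUT, with 0 in the highest other split. Here too the other splits mix groups in which the responding elements differ, which raises their spread. These counts are therefore no evidence on chance either. For 250 ng against 25 ng all 10 splits gave 0 relative calls, the real one included. For ADARcdMUT against no induction 3 of 10 splits gave at least the real 2 calls, and the highest other gave 207. The cause of that count was not tested. On the relative scale, which removes shifts of whole libraries, 3 of 10 splits gave at least the real 2 calls, with 5 as the highest other.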

How the results depend on the processing

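The alternatives on relative values, the minimum of 5000 reads and the deposited score were chosen after seeing the data. Library levels (36 values without and 36 with a library left out), the consensus preference (54 and 36) and the position effects (14) kept their direction and their side of the threshold throughout, though the exact tests of 3 against 3 cannot pass 0.05 and so say nothing about stability. With a library left out, the preference of 250 over 25 ng ranged from 0.02 to 0.09 and that of ADARcdMUT over no induction from -0.17 to -0.06, and the library level of ADARcdMUT over no induction from 0.0661 to 0.186 points. Minimums of 0 and 500 reads removed no element and tested nothing. Of 69 values of named elements 61 kept direction and call and 2 grew weaker. The other 6 changed sign by centring, which for elements with the smallest increases follows from its construction and says nothing about stability. With a library left out 132 of 138 kept both. Replicate variance was 2.73 to 5.79 times the binomial one, a ratio that also holds library-wide shifts and any PCR copies, so the part that depth in molecules plays is open. Where no cause is given, the cause was not tested.

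Centring on the library median, which removes the shared rise by construction, left 131, 93, 0, 148 and 101 calls for 250 ng and 25 ng against no induction, 250 against 25 ng, and 250 and 25 ng against ADARcdMUT. By the same construction the elements that rose less than the median turned negative, ATTGATGT to -0.42, TGTGTGTG to -0.36, ATACGTGT to -0.33, TGTCCAGA to -0.32, TGGATAGA to -0.31 and EMPTY to -0.19. ADARcdMUT against no induction had 0 calls in the quasi-binomial model, 1 on the arcsine scale and 0 with only the 2 groups. With a library left out the calls ranged from 0 to 118. They were 0, 5 and 1 without non-induced replicate 1, 2 or 3, 0 without ADARcdMUT replicate 2 and 118 without ADARcdMUT replicate 3. TATAATTA was lost without non-induced replicate 1 (limma adjusted p = 0.183) or ADARcdMUT replicate 2 (0.0542), and TTTACAAA without non-induced replicate 1 (0.243) or 3 (0.132) or ADARcdMUT replicate 1 (0.0544) or 2 (0.0906). The quasi-binomial adjusted p was 0.576 for both.

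On relative values the arcsine scale gave 153 higher and 63 lower for 250 ng against no induction, 14 lower for 25 ng, 35 higher for 250 against 25 ng, 160 higher and 69 lower for 250 ng against ADARcdMUT, and 0 for ADARcdMUT against no induction. With only the 2 groups in the fit the lower counts were 67 for 250 ng against no induction, 20 and 6 for 250 and 25 ng against ADARcdMUT, and ADARcdMUT against no induction had 0 higher. The share of reads edited gave 12 lower for 25 ng against no induction, and 1 higher and 1 lower for ADARcdMUT. With a library left out, higher and lower counts ranged over 66 to 91 and 12 to 32 (250 ng against no induction), 50 to 68 and 3 to 17 (25 ng). They were 68 to 127 and 12 to 58 (250 ng against ADARcdMUT), 54 to 96 and 9 to 43 (25 ng against ADARcdMUT), and 2 to 11 and 1 to 10 (ADARcdMUT against no induction), and stayed at 0 for 250 against 25 ng. The lower counts were 13, 13 and 12 without fusion 250 ng replicate 1, 2 or 3 against no induction and 14, 16 and 12 against ADARcdMUT. For 25 ng they were 4, 3 and 6 without its replicate 1, 2 or 3 and 9 without non-induced replicate 1 or 3, and against ADARcdMUT 15, 9 and 12, or 41 and 43 without ADARcdMUT replicate 1 or 2. For ADARcdMUT against no induction they were 3, 2 and 1 without non-induced replicate 1, 2 or 3, with 4 higher without replicate 2. They were 11 higher and 10 lower without ADARcdMUT replicate 3, 5 and 1 without replicate 1, and 3 and 1 without replicate 2. At a minimum of 5000 reads the correlation between group means was 0.578 for no induction with ADARcdMUT and 0.153 for 25 ng with ADARcdMUT, and the cause was not tested.

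With the replicate number as a replicate block, 11 elements were lower for 25 ng against no induction. Element by element the numbers gave no sign of pairing: over 18 pairs of same-numbered libraries the correlation ran from -0.0946 to 0.0737, with 0 above 0.1. A shift shared by whole libraries of the same number would not show in this correlation.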

Other observations

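All tests in this part were chosen after the values were seen. In 32 elements the first TGTA starts after position 1, so that the bases following it run out of the element. They lay 0.28 ± 0.01 log2 odds (SD, n = 3) above elements without TGT at 250 ng and 0.25 ± 0.01 at 25 ng. The highest were ATGTATAG at 11.1% ± 0.104, TCTGTATA at 10.6% ± 0.231 and ATGTACAT at 10.5% ± 0.106 at 250 ng, and GGTATGTA, where TGTA fills the last 4 positions, was at 10.4% ± 0.0524. Others lay close to elements without TGT (7.80%), the lowest being TGTGTAGA at 8.005% ± 0.316 and TGTGTATC at 8.08% ± 0.0685. The 149 elements outside the consensus with TGTA at position 1 lay 0.16 ± 0.01 above elements without TGT.

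Base composition is argued against as the cause, since 26 of these elements lay 0.27 above elements without TGT of the same composition (6 of 6 induced libraries, two-sided exact sign-flip permutation p = 0.0312, the smallest possible). A background without the fusion is argued against as the whole cause, since the excess in the 6 other libraries was 0.0464 (5 of 6, exact sign-flip permutation p = 0.0625) against 0.27 in the induced ones. What is left of the consensus read from position 1 is argued against, since 24 of them lay 0.26 above double substitutions at the same positions without TGTA (6 of 6, exact sign-flip permutation p = 0.0312). A candidate explanation is that PUM2 also binds sites that start later and are completed by the flanking reporter sequence, which is not given in the sources used here and was not tested.

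CGTGCATA, TGTGCCTA and GGTAAGTA were picked because their highest group mean, relative to the library median, was the lowest of all elements. That they lay below the library median in 12 of 12 libraries follows largely from this choice. They were at 6.41% ± 0.123, 6.56% ± 0.237 and 5.82% ± 0.309 at 250 ng (SD, n = 3) and 1.33% ± 0.138, 1.44% ± 0.201 and 1.49% ± 0.1804 without induction. The log2 share of reads of consensus elements, against elements without TGT with the same number of G and C, was 0.14 ± 0.03 without induction and 0.18 ± 0.04 at 250 ng (difference 0.04, two-sided exact permutation p = 0.40).

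Editing also became denser per read. The median share of reads with at least 1 edit was 6.99% ± 0.118 without induction, 13.8% ± 0.102 at 25 ng, 22.3% ± 0.402 at 250 ng and 7.18% ± 0.339 with ADARcdMUT alone, and an edited read carried 1.83 ± 0.0777, 2.20 ± 0.0925, 2.48 ± 0.0176 and 1.89 ± 0.0336 edits.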
